A study of Homo sapiens with 2 samples.

How the data were processed

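Gene expression was measured in HT29 cells, a human colorectal adenocarcinoma line, on 2 Affymetrix arrays of 54675 probe sets each. Per the labels, 1 array held RNA from cells transfected with siHX to knock down the human endogenous retrovirus HERV-HX, and 1 array held RNA from control cells, and both cultures grew in RPMI medium with 10% serum. What the control cells received beyond the shared statement that cells were transfected with siRNAs is not given in the sources used here. Total RNA was taken with Trizol, cleaned on a column and labelled with biotin by the one-cycle method, per the labels' protocols.

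The deposited value table holds linear signal intensities, made by the authors with GCOS, per the submitters' processing notes; its version and settings are not given in the sources used here. On both arrays the mean signal without the lowest and highest 2% of probe sets was 500, so both arrays had been scaled to a common target. This scaling sets the overall level of the 2 arrays equal by construction and cannot show a change in total mRNA. The authors also deposited a table of probe sets listed as higher, another of those listed as lower, and a table of their log2 fold changes. Per the file headers, that log2 value (Signal Log Ratio) compares each probe pair of the siHX array with the same pair on the control array, and a value of 1.0 is a 2-fold increase. The deposited lists also carry p-values from the authors, for detection on 1 array and for change between the 2 arrays. They come from the probe pairs of these arrays and hold no information on the spread between cultures. Detection calls came with the listed probe sets only. The signals in the lists were equal, digit for digit, to those in the value table for all 548 listed probe sets.

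From the deposited signals, the log2 ratio of the siHX array to the control array was computed per probe set, without a pseudocount. The 62 AFFX control probe sets were left out, which left 54613. A probe set was called measured when its signal was at or above the median of all probe sets on its own array, 118.5 on the siHX array and 109.7 on the control array. Because detection calls did not cover all probe sets, this floor was the filter fixed for that case. A probe set measured on 1 array only was given as an at-least fold, the bright signal over the floor of the other array, and counted apart. Gene symbols came from the platform annotation, brought up to date through Entrez gene numbers and the RefSeq gene table of GRCh38.p14: 41091 probe sets had 1 symbol, 1801 had several and 11721 had none in the annotation used. Only probe sets with 1 symbol were named. One probe set stood for a gene, the measured one with the highest mean log2 signal.

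Each group held 1 array, so there was no replicate check and no test between groups, and no p-value of this work is given. Differences were described by size, with 2-fold as the threshold. The only internal measure of error was the SD of the log2 ratio between probe sets of 1 gene, which covers technical spread within the 2 arrays and leaves out the spread between cultures, labellings and arrays. For 30 gene lists fixed before the data were examined, the median log2 ratio was placed as a percentile among 10000 random lists of the same size, matched on mean signal in 20 bins. A list needed 5 measured genes, and 5 lists had fewer. Percentiles describe these 2 arrays, not the conditions. Intervals of list medians are exact order-statistic intervals at 95%, and shares carry exact Clopper-Pearson intervals at 95%; with 5 genes the interval of a median is the whole range and covers slightly less. The number of arrays limits the precision of every value.

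The genes named were set by a rule fixed before the data were examined. Per direction it took the 15 genes with the largest log2 ratio measured on both arrays, at least 2-fold, leaving out probe sets with the suffix _x_at, which can bind several transcripts. It added the 5 genes per direction with the largest at-least fold, up to 4 members of each gene list, the 5 top entries of each of the authors' lists, and the genes tied to endogenous retroviruses. Members of gene lists could rest on probe sets with the suffix _x_at. Genes named beyond the rule are said to be so where they appear. Alternatives were median centring, quantile normalisation, a loess fit on mean signal (span 0.4), log2(signal + 50), floors at the 25th and 75th percentile or none, folds of 1.5 and 3, leaving out probe sets by suffix, and the median over a gene's probe sets. Scaling on the poly-A controls, the brightest probe set per gene and a restriction to the authors' lists were added after seeing the data.

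The code was tested on simulated arrays with the real signals and a noise SD of 0.2 per array on the log2 scale, less than the data hold, with changes set in bright probe sets. It recovered 99% of probe sets changed 3-fold and all of those changed 4-fold, and called 7 of 26246 unchanged probe sets. Of 24 simulated lists without a shift, 2 fell outside percentiles 2.5 to 97.5, so percentiles close to these bounds carry little weight. The simulated noise was independent between probe sets, so it cannot show how lists of genes that vary together would fall. In the data 10 of 25 lists fell outside, the housekeeping list among them. With the log2 ratio given the within-gene SD of 0.36, 80 of 25866 unchanged probe sets were called higher and 73 lower, and with the robust SD of each of 4 signal ranges (0.46 to 0.28) 154 and 144 of 25598. Among probe sets of any measured signal, 81.5% and 77.5% of those changed 3-fold were then recovered. These SDs also hold real differences, between transcripts of a gene or between the arrays. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used. No genome build applies to these probe set values, so no coordinates are given.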

Results

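Transcript levels were compared between HT29 colon cancer cells transfected with siHX and control HT29 cells, with 1 array per group and no replicates. The comparison asks which transcripts differ when the retroviral transcript HERV-HX is targeted by an siRNA. HERV-H is a family of endogenous retroviruses, the remains of ancient infections of the germ line. After the filter on dim signals, 24874 probe sets were measured on both arrays and stood for 11368 named genes. Log2 signals of these probe sets correlated across probe sets with r = 0.970, where probe sets are not independent replicates.

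The level of the target itself could not be read from the annotation, in which 0 probe sets had HERV in their symbol. Among genes tied to endogenous retroviruses, ERVK13-1 and GSDMB were measured on both arrays. The brightest ERVK13-1 probe set gave 336 on the siHX array and 125 on the control array, 2.68-fold higher, while a dimmer one gave 137 and 203. GSDMB, a gasdermin gene, was 1.52-fold higher on its brightest probe set, with 976 against 640, and a second one gave 588 against 201, while the third was above the floor on the control array alone (65.2 against 119). ERVH48-1 had signals of 3.2 and 51.6, both under the floor, so no fold is given. HHLA1, HHLA2, ERV3-1 and ERVFRD-1 also lay under the floor on both arrays, and ERVW-1 reached it with 1 probe set on the siHX array alone (122 against 85.7).

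Among the largest differences, ADM (adrenomedullin, a vasodilator peptide) was 4.07-fold and ANGPTL4, an inhibitor of lipoprotein lipase, 3.69-fold higher on the siHX array, and both are known to respond to low oxygen. EDN2 (endothelin 2), HILPDA, a lipid droplet protein, and COXFA4L2, also known as NDUFA4L2, were 4.44-fold, 2.69-fold and 2.55-fold higher. Lower were enzymes of serine, asparagine and cysteine synthesis, namely PSAT1 (3.53-fold), ASNS (3.64-fold) and CTH (3.53-fold), together with the cystine transporter SLC7A11 (3.03-fold). The arrestin-like genes TXNIP and ARRDC4, both known as glucose-responsive, were 2.54-fold and 4.17-fold lower. In all, 513 of the 24874 probe sets (2.06%) were at least 2-fold higher and 179 (0.720%) at least 2-fold lower, and 97.2% lay within 2-fold. The higher ones were 74.1% of those past 2-fold, 62.6% after quantile normalisation, and 4.25% (79 against 1779 lower) when scaled on the poly-A controls, an alternative chosen after seeing the data. Per gene, 130 were higher and 59 lower. Among 25866 unchanged probe sets of simulated arrays, 80 were at least 2-fold higher and 73 lower at the within-gene SD. Among 25598 at the robust SD of each signal range, the counts were 154 and 144. Single probe sets near 2-fold thus cannot be told from noise in either direction. In the data the 6219 dimmest probe sets had a median log2 ratio of 0.099, with 216 at least 2-fold higher and 61 lower. The 6219 brightest had -0.042, with 55 and 25. The simulated counts were close to equal, so they do not carry this difference and cannot show which direction holds more noise. Agreement between probe sets of a gene, given below, was 58.2% on the lower side and 45.0% on the higher.

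Other genes among the 15 largest on the higher side were RRP12, RELT, NEURL3, NEK8, ZNF414, CCDC24, LOC389765, KISS1R and PPFIBP1, between 2.62-fold and 3.16-fold, and ERVK13-1. All of these had control signals of 116.3 to 397.2, where the floor was 109.7. For NEK8, RRP12 and PPFIBP1 the brightest probe set was of the type left out by the rule and gave a smaller log2 ratio, 0.89 (under 2-fold), 1.08 and -0.078, and a dim RRP12 probe set gave -0.59. Among the 15 largest on the lower side were also MCPH1-AS1, DUS4L, FAM241A, CLIC4, AKTIP, FAM86C1P and G0S2, between 2.57-fold and 3.47-fold. FLOT1 and DIMT1 were 3.03-fold and 2.68-fold lower on the probe set the rule chose, but their brighter probe sets, of the type left out by the rule, had log2 ratios of -0.19 and -0.34 for FLOT1 and -0.53 and -0.15 for DIMT1. TXNIP was lower on all 3 of its measured probe sets, with log2 ratios of -1.35 to -2.25, and PSAT1 and SLC7A11 on both of theirs.

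**Figure D1:**
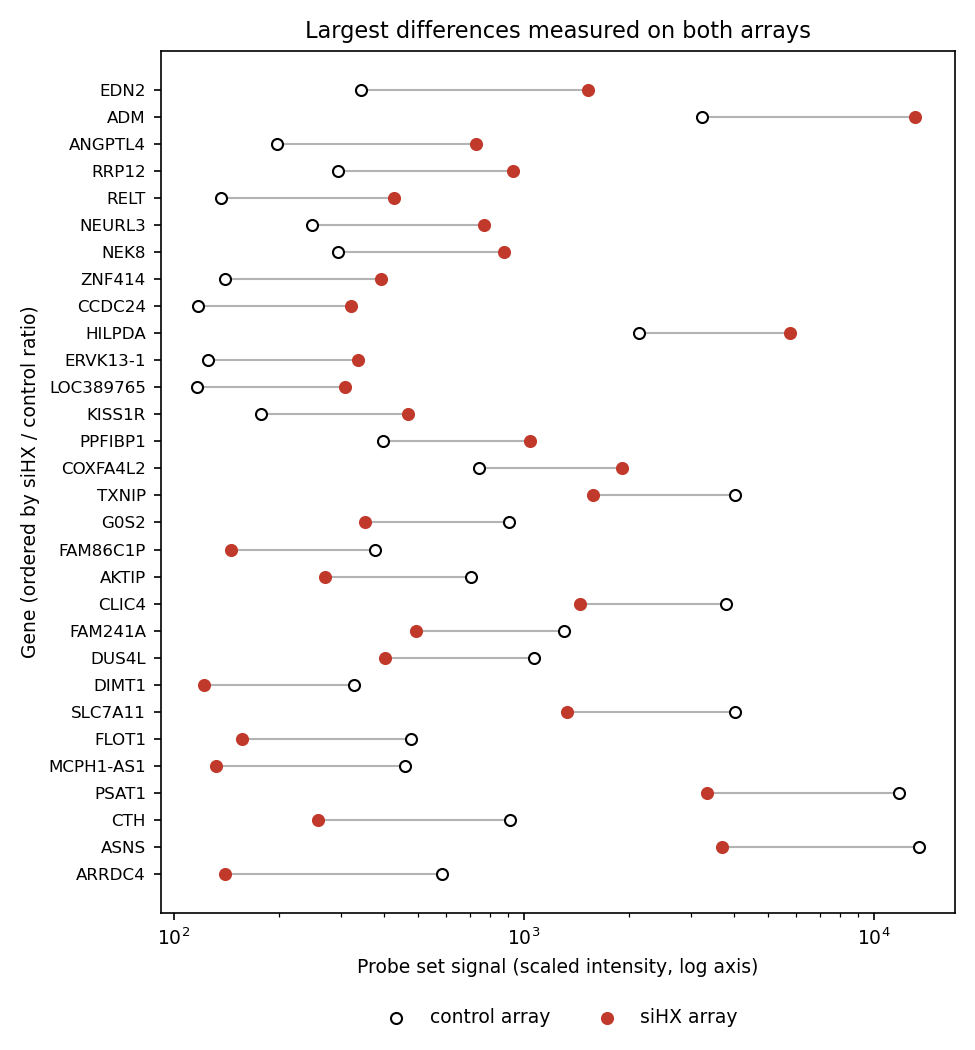
Signal of the 30 genes with the largest differences measured on both arrays, on a log axis; open circles are the control array and filled circles the siHX array, 1 array each. EDN2, ADM and ANGPTL4 head the higher side, and ARRDC4, ASNS and CTH lie at the other end.

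Some transcripts were measured on 1 array only. HSPA6, a strictly inducible heat shock protein, had a signal of 945 on the siHX array and 7.9 on the control array, at least 8.62-fold higher, and its second probe set gave 498 against 74.7. UTS2R, U2AF1L4, NOMO3 and GAL3ST1 were at least 4.31-fold, 3.36-fold, 3.16-fold and 3.07-fold higher. On the lower side LOC389199, the kinase gene PIM2, ELOA-AS1, the immediate early gene EGR4 and CRMP1 were at least 3.55-fold, 3.29-fold, 3.15-fold, 2.83-fold and 2.74-fold lower. EGR4 rested on 1 of 3 probe sets, the other ones being under the floor on both arrays. In all, 220 probe sets were measured on the siHX array alone and at least 2-fold higher, and 81 on the control array alone and at least 2-fold lower.

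A single list held genes of the response to low oxygen and of glycolysis, and it was higher as a group. Whether the glycolysis genes alone were higher was not tested. On the brightest probe set of each gene, all 23 measured members had ratios above 0, with a median log2 ratio of 0.49 (95% interval over genes 0.25 to 0.79), above all 10000 matched random lists, whose middle 95% ran from -0.17 to 0.07. ADM, ANGPTL4 and ENO2, a neuronal-type enolase (2.27-fold), passed 2-fold, and none was 2-fold lower. The prolyl hydroxylase gene EGLN3 was 1.87-fold higher, though its second probe set gave a log2 ratio of -0.0041. PGK1, ENO1 and TPI1, chosen after their values were seen, also had probe sets on both sides of 0, and their medians over probe sets were 0.11, -0.13 and 0.099. Over the 10 members with a second measured probe set, those second ones had a median of 0.15. Of the bright glycolytic genes, LDHA, chosen after its values were seen, gave 42373 against 41988 and GAPDH 42082 against 40865. Beside this list and the others, the arrays differed in 1 of 2 signs of RNA quality. The ACTB 3'/5' signal ratio was 3.80 (siHX) against 2.92, while that of GAPDH was 1.28 against 1.31. The 18S ribosomal RNA probe sets were 3.15-fold to 4.49-fold lower on the siHX array. Scaling on the poly-A controls would lower every log2 ratio by 0.47, so each direction given is relative to the overall level of the arrays. On that scale the list's median would be 0.020, and it would be the 1 median of 25 above 0.

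Genes of the amino acid and unfolded protein stress response were lower as a group, with a median log2 ratio of -0.38 (-1.12 to -0.13) over 25 measured genes, below all 10000 random lists. Of these, 8 were at least 2-fold lower on their brightest probe set and 0 at least 2-fold higher. The 8 were ASNS, CTH, PSAT1 and SLC7A11 and, named after their values were seen, TRIB3, MTHFD2, SLC7A5 and CHAC1, with log2 ratios of -1.12 to -1.27; most of these serve amino acid synthesis, one-carbon metabolism or amino acid transport. The 5 members with ratios above 0, also named after their values were seen, were DDIT3, the gene for the stress factor CHOP, with a log2 ratio of 0.97, PPP1R15A (0.62), the chaperone gene HSPA5 (0.58), DDIT4 (0.52) and VEGFA (0.35). ATF4, the transcription factor gene of the amino acid response and likewise named after its value was seen, had -0.13.

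Mitotic genes were lower by a small amount. Of 34 measured, 30 had ratios below 0, with a median log2 ratio of -0.35 (-0.52 to -0.25), below all random lists. None reached 2-fold on its brightest probe set, though a dimmer MAD2L1 probe set, named after its values were seen, gave -1.06. The largest on the brightest probe sets were the centromere histone gene CENPA (1.94-fold lower), the cyclins CCNB1 and CCNA2 (both 1.62-fold) and CKAP2 (1.62-fold). CENPA rested on 1 measured probe set, with the suffix _x_at. Genes of DNA replication and the G1/S transition had a median of 0.11 (0.019 to 0.26, 97.6th percentile) over 29 genes. On the brightest probe sets it was led by CCNE2 (1.84-fold higher), ORC1 (1.72-fold), CDC25A (1.71-fold) and CHAF1A (1.60-fold, suffix _x_at). Control signals of CCNE2 and ORC1 were 169 and 142.5, where the floor was 109.7. RFC3, 1 of 8 members below 0 and named after its values were seen, had -0.28 and -1.85 on its 2 probe sets. Alternatives put this list as low as percentile 96.8, inside the random range. Among the 4 mitotic genes above 0, chosen after their values were seen, MKI67, TOP2A and CENPF had log2 ratios of 0.35, 0.28 and 0.33 and TTK 0.071.

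Cholesterol synthesis genes were higher, with a median log2 ratio of 0.40 (0.20 to 0.72) over 17 genes, above all random lists, and 15 of 17 above 0. SQLE, squalene epoxidase, was 2.33-fold higher, HSD17B7 2.08-fold, INSIG1 1.69-fold and MSMO1 1.67-fold, and the median log2 ratio over the 4 SQLE probe sets was 0.83, under 2-fold. HSD17B7 rested on 1 measured probe set, with the suffix _x_at. The 9 measured fatty acid synthesis genes also had a median of 0.40 (-0.22 to 0.66), led by FASN (1.77-fold), SREBF1 (1.58-fold), ACLY (1.46-fold) and SCD (1.34-fold), but the median over each gene's probe sets turned this to -0.037.

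**Figure D2:**
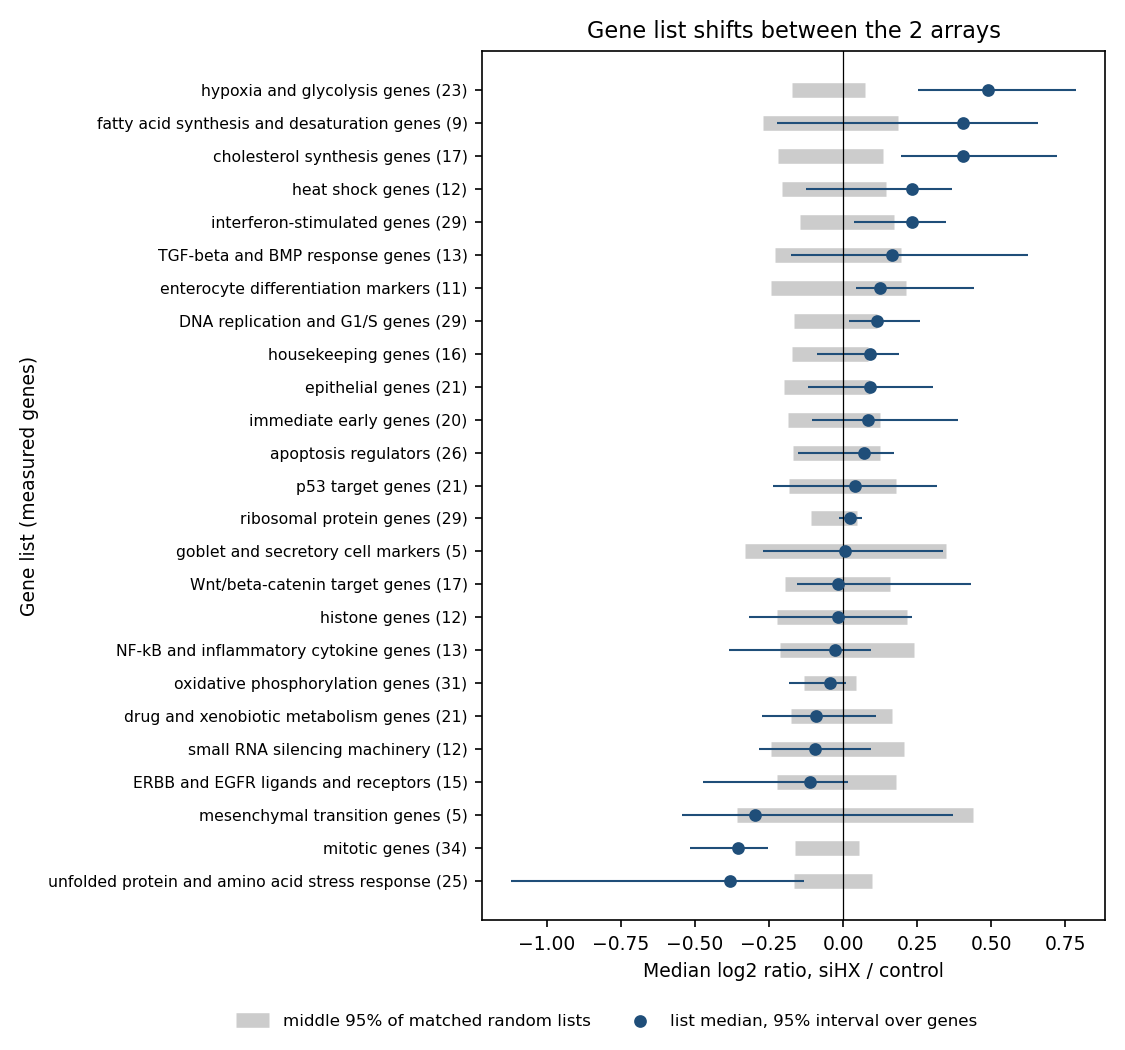
Median log2 ratio of siHX to control for each of the 25 gene lists with enough measured genes, with the 95% interval over genes as a line and the middle 95% of matched random lists as a grey bar. Hypoxia and cholesterol genes lie to the right of their bars (medians 0.49 and 0.40), and mitotic and amino acid stress genes to the left (-0.35 and -0.38).

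**Figure D3:**
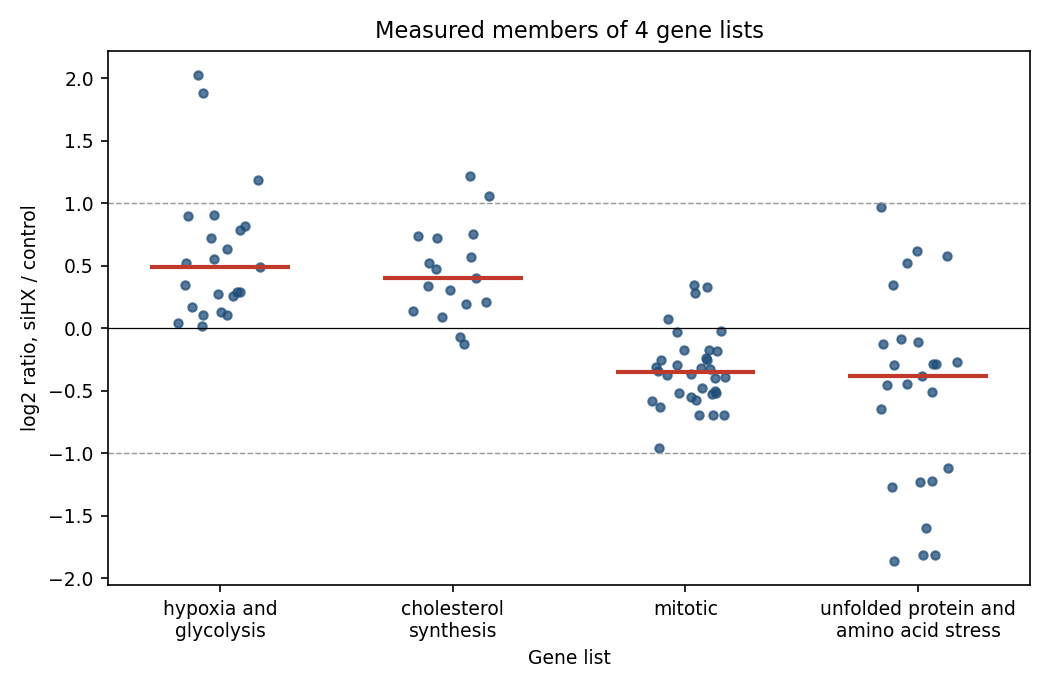
Log2 ratio of siHX to control for every measured member of 4 gene lists; each point is a gene by its brightest probe set, the red line is the list median and dashed lines mark 2-fold. All 23 hypoxia and glycolysis genes lie above 0, and 30 of the 34 mitotic genes lie below it.

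Interferon-stimulated genes, part of the antiviral response, had no member past 2-fold among 29 measured, by the brightest probe set of each gene. RIGI, named after its values were seen, had a log2 ratio of -0.085 on its brightest probe set. Its 3 measured probe sets reached up to 1.05, past 2-fold. The list had a median log2 ratio of 0.23 (0.035 to 0.35, 99.5th percentile), with 23 above 0. With other floors the median was as low as 0.13, at percentile 95.25, inside the random range. IFI6, MX1 and IFI27 were 1.77-fold, 1.75-fold and 1.72-fold higher, and the RNA sensor gene IFIH1 was 1.46-fold lower. Heat shock genes had a median of 0.23 (-0.12 to 0.37, 99.8th percentile) over 12, where HSPA4 (1.42-fold), HSPB1 (1.33-fold) and HSP90AA1 (1.29-fold) were higher and HSPA4L was 1.47-fold lower. The small RNA silencing machinery had a median of -0.095 (27.3rd percentile), with PRKRA 1.61-fold, TNRC6A 1.27-fold and TNRC6C 1.22-fold lower and TNRC6B 1.20-fold higher on their brightest probe sets.

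The lists of growth and signalling genes lay inside the random range, while some members differed more. MYC was 2.09-fold lower and the Wnt target AXIN2 1.75-fold lower, while RNF43 and PLAUR were 1.55-fold and 1.44-fold higher, and the Wnt target list had a median of -0.017 (53.3rd percentile). EREG, an EGFR ligand, was 2.43-fold lower, ETV5 1.73-fold, BTC 1.61-fold and HBEGF 1.39-fold, with a list median of -0.11 (21.7th percentile). Among immediate early genes (median 0.082, 93rd percentile), DUSP5 was 2.29-fold and JUN 1.54-fold higher and EGR1 1.47-fold lower. In the NF-kB list (median -0.029, 38.5th percentile), the chemokine gene CXCL1 was 2.31-fold and TNFAIP3 1.42-fold higher, and SOD2 and IL1A were 1.61-fold and 1.49-fold lower. TGF-beta and BMP response genes had a median of 0.16 (95.7th percentile), with TGFB2 (1.65-fold), BMP2 (1.58-fold) and TGFB1 (1.54-fold) higher and ID1 lower (7546 against 11346).

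Among p53 target genes (median 0.039, 68.9th percentile), GDF15 was 2.05-fold, CDKN1A 1.62-fold and PLK3 1.49-fold higher and TIGAR 1.68-fold lower. Apoptosis regulators had a median of 0.071 (90.4th percentile), where TNFRSF10A (1.98-fold) and BMF (1.58-fold) were higher and CYCS was 1.32-fold lower. CFLAR was 1.92-fold lower on its brightest probe set, but its 11 probe sets had both signs and a median log2 ratio of 0.22. Histone genes had a median of -0.018 (47.7th percentile), with H2AC8 2.15-fold and H1-2 1.34-fold higher and H3-3A and H2BC21 2.05-fold and 1.61-fold lower. For drug metabolism genes (median -0.093, 16.2nd percentile), CYP3A5 was 1.84-fold, AKR1C2 1.51-fold and ABCC3 1.30-fold higher and ALDH1A1 1.42-fold lower. Oxidative phosphorylation genes had a median of -0.046 (44.9th percentile) and their largest ratios, SDHD, CYC1, NDUFA9 and NDUFV2, were 1.21-fold to 1.30-fold lower.

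Among markers of cell type, epithelial genes had a median of 0.090 (97.6th percentile, and 83.8 with the median over probe sets), with ELF3 1.75-fold higher, CLDN4 higher (4355 against 2935) and CLDN1 and TJP1 1.72-fold and 1.37-fold lower. Enterocyte markers had a median of 0.13 (90.8th percentile), with CEACAM7 2.12-fold, CA2 1.36-fold, VIL1 1.21-fold and DPP4 1.19-fold higher. The 5 measured goblet and secretory markers had a median of 0.0072 (52.5th percentile), from AGR2, 1.21-fold lower, to MUC13, 1.26-fold higher, with SPDEF and MUC5AC between them. Mesenchymal genes had a median of -0.30 (4.47th percentile) over 5, among which TNC, MMP9 and FN1 were 1.46-fold, 1.24-fold and 1.23-fold lower and S100A4 1.29-fold higher. Alternatives put the mesenchymal median between -0.38 and -0.090 and its percentile between 2.85 and 25.55. Too few genes were measured for markers of fibroblasts (4: TAGLN 251 against 195, COL1A1 370 against 437, THY1 136 against 150, ACTA2 258 against 272), endothelium (3: ENG 696 against 405, PECAM1 297 against 196, TEK 129 against 142), immune cells (2: LYZ 24382 against 24261, CD79A 246 against 288) and enteroendocrine cells (1: PAX4 222 against 168), siHX first in each pair.

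Control genes and controls on the array set the scale for these values. GAPDH gave 42082 on the siHX array and 40865 on the control array on its brightest probe set, and the 3 measured ACTB probe sets had log2 ratios of 0.071 to 0.088. Ribosomal protein genes had a median of 0.024 (92.8th percentile), which median centring turned to -0.021, with RPL19, RPL3 and RPS16 up to 1.08-fold higher and RPLP2 1.67-fold lower on a dim probe set. Housekeeping genes had a median of 0.090 (97.9th percentile, and 85.3 with the median over probe sets), where TUBB was 1.33-fold lower and POLR2A, LMNA and YWHAZ 1.29-fold, 1.27-fold and 1.27-fold higher. The signal at the 3' end over the 5' end was 1.28 and 1.31 for GAPDH, siHX first, unlike the ACTB ratios given above. Beside the lower 18S probe sets, the 2 for 28S ribosomal RNA with signals above the floor were 1.36-fold and 1.33-fold lower, the third being under it on both arrays.

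Probe sets of the same gene gave an internal view of technical error. Across 5310 genes with several measured probe sets, the SD of the log2 ratio within a gene was 0.36, against an SD of 0.42 over all probe sets. Of 211 genes with a probe set at least 2-fold higher, 95 had all their other probe sets on the same side (45.0%, exact interval 38.2 to 52.0), where random signs would give 30.6%. For 110 genes with a probe set at least 2-fold lower the count was 64 (58.2%, 48.4 to 67.5), against 29.5%. The spread fell with signal, from an SD of 0.48 for the 6219 dimmest probe sets to 0.34 for the 6219 brightest. Among the list members named, the probe sets of CDC25A, ETV5, BTC, PLAUR, EGR1, CFLAR, CYCS, EGLN3, ACLY, SCD, DPP4, AGR2, HSPA4, LMNA, YWHAZ, LYZ, COL1A1, THY1, PRKRA, TNRC6A, TNRC6B, MKI67, TOP2A, CENPF and RIGI lay on both sides of 0. Of the genes named as at least 2-fold different, SQLE, GDF15, EREG, ERVK13-1, RRP12, PPFIBP1, AKTIP, FLOT1 and DIMT1 were under 2-fold by the median over their probe sets.

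The authors' deposited table of higher probe sets held 414 entries and that of lower ones 134, each with a log2 ratio of at least 1 in size. All 414 were called Present on the siHX array in the authors' deposited table and 165 were Absent on the control array, while all 134 of the lower list were Present on the control array and 66 Absent on the siHX array. The ratio recomputed from the signals had the listed direction for 413 of 414 (99.8%, exact interval 98.7 to 99.99) and for 134 of 134 (97.3 to 100), and it reached 2-fold for 327 (79.0%, 74.7 to 82.8) and 105 (78.4%, 70.4 to 85.0). The single exception, named after its values were seen, was a PPP6R2 probe set, with 1070 against 1164. Conversely, 192 of the 513 probe sets at least 2-fold higher and 48 of the 179 lower were in the authors' lists, and so were 10 and 12 of the 15 genes named per direction.

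In the authors' deposited table the largest values on the higher side were 6.5 for HSPA6, 5.4 for TAPT1, 4.9 for ARID5B, 4.5 for GPNMB and 4.3 for DCLK1, on the log2 scale. On the lower side the authors' deposited table gave -4.6 for UCHL5, -4.2 for SNHG33, -4.1 for a probe set without a gene symbol, -4.0 for APOF and -3.9 for GATM. Apart from HSPA6, these probe sets had signals of at most 115 on the siHX array and 146 on the control array, and each was Absent on 1 array, so their size rests on signals between 1.6 and 5.5 on the dim side.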

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

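The statement on the cultures, the tests of scaling on both gene lists, the scaling on poly-A controls and the tests that use the brightest probe set of each gene were chosen after seeing the data; the remaining tests were laid down before their results were seen, on patterns already seen. Outside the main comparison, the poly-A control probe sets, for RNAs added before labelling, were brighter on the siHX array on all 24 probe sets, with a median log2 ratio of 0.47. Control probe sets for the later hybridisation step were brighter on 17 of 18, with a median of 0.18.

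In the list of hypoxia and glycolysis genes, 23 of 23 measured members were higher on the siHX array on their brightest probe set, while ENO1, chosen after its values were seen, was lower by the median over its probe sets (-0.13). Its median kept an interval above 0 under median centring, quantile normalisation and loess but was 0.020 (-0.22 to 0.32) on the poly-A controls, whose amounts are unknown, so the scaling stays open for its direction against 0. The second brightest probe sets, which 10 members have, gave a median log2 ratio of 0.15 (96.5th percentile), smaller than on the brightest ones, so probe sets that measure something else stay open for part of the list. EGLN3 had 0.91 on its brightest probe set and -0.0041 on the other, while SLC2A1, chosen after its values were seen, had 0.17 and 2.01. With 1 array per group, a difference between the cultures such as density, oxygen or medium may produce the same pattern as the siRNA, and these cannot be told apart.

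The lower amino acid stress genes were tested in the same way. Of the list's medians under median centring, quantile normalisation, loess and poly-A scaling, the one closest to 0 was -0.33 (-1.14 to -0.17) with loess. The direction thus held under each of these scalings. The first ones shift the ratios by a median of only -0.045, -0.042 and -0.025, and poly-A scaling by -0.47, away from 0. None could have brought this list to 0, so the scaling as a cause is not decided by them. Second probe sets of 9 members had a median log2 ratio of -0.61, below all random lists of second probe sets. This argues against faulty single probe sets for these 9 as a set. ASNS, CTH, CHAC1, SLC7A5 and MTHFD2, all at least 2-fold lower, had only 1 measured probe set each and were not covered. The state of the cultures, such as the amino acids left in the medium, again rests on 1 array per group and cannot be told apart from the siRNA.

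The third pattern is the excess of higher over lower probe sets, 2.87 to 1, which was 2.95 with log2(signal + 50), 3.25 at 3-fold and 3.47 without _x_at and _s_at probe sets, but 1.94 with median centring, 1.84 with loess, 1.78 with the floor at the 25th percentile, 1.74 at 1.5-fold and 1.24 with no filter, and turned to 79 higher and 1779 lower on poly-A scaling. Quantile normalisation lowered it to 1.68 (interval from counts 1.42 to 1.97). The brightest probe set of each gene gave 2.20 (1.61 to 3.05), and a floor at the 75th percentile gave 2.39 (1.66 to 3.48). None of the 3 accounts for all of it and none is excluded. The intervals treat probe sets as independent and hold no spread between arrays or cultures. Applied together, quantile normalisation and the brightest probe sets left 100 higher and 71 lower, a ratio of 1.41 (1.03 to 1.94). The brightest probe set setting also drops the probe sets without a symbol, so it cannot show that probe sets outside the main transcripts were the source. Among named genes, 130 brightest probe sets were higher and 59 lower, and of the remaining ones 184 were higher and 92 lower. Unnamed probe sets were at least 2-fold higher in 5.20% (180 of 3461) and lower in 0.607% (21), against 1.54% and 0.740% of named ones. The arrays also differed in the ACTB 3'/5' ratio (3.80 against 2.92), but little in that of GAPDH (1.28 against 1.31). The 18S ribosomal RNA was 3.15-fold to 4.49-fold lower on siHX. A difference in RNA quality, like unspliced or unannotated RNA in the siHX sample, stays open.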

How the results depend on the processing

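Poly-A scaling, the brightest probe set per gene and the authors' lists were chosen after seeing the data; the cause of each change below was not tested beyond what the setting itself does. The counts of probe sets at least 2-fold higher (513) and lower (179) depended on the dim-signal filter. They were 2160 and 1213 with the floor at the 25th percentile, 105 and 44 at the 75th, and 8114 and 6559 with no filter. With log2(signal + 50), which leaves the filter as it was, the counts were 280 and 95. They were 2391 and 1375 at 1.5-fold, 52 and 16 at 3-fold, 79 and 1779 on poly-A scaling, 130 and 59 for the brightest probe set per gene, and 192 and 48 within the authors' lists; without _x_at and _s_at probe sets they were 361 and 104. Median centring, quantile normalisation and loess gave 402 to 427 higher and 220 to 240 lower. Probe sets measured on 1 array and at least 2-fold numbered 2037 (siHX) and 1545 (control) with the floor at the 25th percentile and 23 and 7 at the 75th, against 220 and 81. The share of genes whose probe sets lay on 1 side was 28.2% (higher) and 25.1% (lower) with no filter and 61.8% and 81.2% with the floor at the 75th percentile. Of the list medians recomputed, 2 left the interval of the value reported, the ribosomal list at -0.021 with median centring and the goblet list at -0.29 with the floor at the 25th percentile. The fatty acid list turned to -0.037 with the median over probe sets, inside its wide interval, and the other 170 stayed within theirs. Hypoxia, cholesterol, mitotic and amino acid stress lists stayed beyond all random lists in all 7 settings, while the interferon (percentile 95.25 to 99.95), housekeeping, epithelial and replication lists entered the random range in some. Median centring shifts every ratio alike, so it could not change the place of a list among the random ones. Quantile normalisation and loess shifted ratios by a median of only -0.042 and -0.025. Of the log2 ratios of named genes under alternatives, 662 moved by less than the within-gene SD. The other 18 moved by more, all 18 with the median over probe sets. Among genes at least 2-fold different none changed sign. Under median centring, quantile normalisation, loess or log2(signal + 50), some of them fell under 2-fold. At their smallest, the log2 ratios were 0.97 for CXCL1, 0.85 for H2AC8, 0.94 for CEACAM7, 0.99 for GDF15 and -0.94 for H3-3A. For smaller differences, the median over probe sets turned the sign of ACLY (-0.11), AGR2 (0.13), CFLAR (0.22), COL1A1 (0.32), LYZ (-0.23) and YWHAZ (-0.25). No paired analysis was possible because each group held 1 array, and leaving out a replicate was not possible for the same reason.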

Other observations

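The probe sets and the signal range described here were chosen after seeing the data. Some probe sets without a gene symbol had large ratios while measured on both arrays. The probe set 240991_at had a signal of 16779 on the siHX array and 3344 on the control array, 5.02-fold higher, and 1558418_at had 1039 against 185, 5.61-fold higher. On the other side 213350_at was 9.23-fold lower, with 615 against 5680, and 222968_at was 3.08-fold lower. The authors' deposited table lists all 4, with log2 ratios of 2.3, 2.2, -2.6 and -1.0. Whether any of them covers retroviral sequence was not analysed here.

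Very bright probe sets differed little. Of 327 with a mean signal of 20000 or above, 1 differed by 1.5-fold or more (0.306%) and 0 by 2-fold, with an SD of the log2 ratio of 0.14, against 7.42% and an SD of 0.34 for the 4256 between 2000 and 20000. LDHA and GAPDH lie in this range, and whether the signal is compressed there was not tested.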
